A study of Homo sapiens with 113 samples.

How the data were processed

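RNA of CD4+ T cells was measured on 113 whole-genome expression arrays (Affymetrix HG-U133 Plus 2.0, short oligonucleotide probe sets with a 3' bias). The donors were patients with clinically isolated syndrome (CIS), a first attack of demyelination that can precede multiple sclerosis, and healthy controls. Per the labels' protocols, blood mononuclear cells were separated on a density gradient and stored frozen. CD4+ cells, called naive in the labels, were then isolated untouched with magnetic beads that remove other cells, their purity was checked by flow cytometry, and the extracted RNA was amplified and labelled with biotin.

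The deposited table holds log2 values, 1 for each of 54675 probe sets and each array, and these ran from 1.68 to 14.6. The deposited values lay on a similar scale on all arrays but 1, with interquartile ranges of 3.03 to 3.66 log2, although array medians were higher in controls at year 1 than at baseline by 0.0440 (adjusted p = 0.0267). The method of background correction, normalisation and summarisation is not given in the sources used here. The values were not normalised again, and no pseudocount was needed. Each column was matched to its sample by name, and 0 columns stayed without a sample.

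The labels gave 39 arrays of 37 CIS donors and 30 arrays of 28 control donors at baseline, and 34 arrays of 33 CIS donors and 10 arrays of 10 control donors about a year later. Donor codes in the labels tied the arrays of a donor together, so 32 CIS donors and 10 control donors had both time points. All 10 control donors carried the time code T2 at year 1, but only 9 of the 33 CIS donors did, the others T3 to T5, and the codes are not defined in the labels used here. Arrays of a donor at baseline, or at year 1, were averaged, so that n counts donors. At year 1 this joined 2 arrays of 1 CIS donor with different time codes, which correlated at 0.990 with a median absolute log2 difference of 0.152. Repeat arrays at baseline correlated at 0.993 to 0.994 across the genes tested below and had median differences of 0.128 to 0.136, and 0 columns were identical. Arrays of different donors of a group had median differences of 0.232 to 0.398. No counting depth exists for arrays, and the number of arrays limits the precision.

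The pairing of the time points came from the donor codes and was checked on 102 probe sets of 54 genes whose signal is known to differ stably between people. With the 10 leading axes of common variation removed, 37 of 41 year-1 donors matched their own baseline array best, against 0.631 by chance. Without that removal 19 of 41 did so.

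Probe sets were named from the platform annotation, with symbols updated through Entrez identifiers. Of the 54675 probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 had none, and 41043 of those with 1 symbol matched an entry of the current RefSeq gene table. Genes with XIST or Y linkage were left out (59 probe sets). Each of 19740 genes was represented by its probe set of highest mean, and the 12638 genes above the median of all probe sets (4.99 log2) were tested. Gene positions were used here only for the length of genes.

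Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, two-sided), with tables read by the data.table package (version 1.17.8), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. CIS and control donors were compared at baseline and at year 1. Year 1 was compared with baseline within CIS donors and within control donors, with the donor as a block. The change of CIS donors was compared with the change of control donors on differences within donors. The 32 gene lists, 25 of T cell programmes and 7 of markers of other blood cells (monocytes, B cells, cytotoxic lymphocytes, dendritic cells, platelets, erythroid cells and neutrophils), were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 32 lists of a comparison. Single quality measures and the spread of list scores were compared with two-sided permutation tests of 100000 resamples. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

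The groups, tests, gene lists, alternatives and the rule for named genes were set before the data were examined. That rule takes, for each comparison, the 10 called genes with the largest log2 change in each direction, the 4 members with the smallest p in the direction of each list that passed, and TOB1, BTG1, KLF2 and CDKN1B in every comparison, because the study is known for a question about T cell quiescence. Other probe sets of a named gene above the same signal level were compared in sign, and disagreements are stated with the gene. For values between groups, a donor count gives the CIS donors on the stated side of the control mean.

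A year-1 CIS array had a median correlation of 0.0535 with the other arrays, against 0.852 for the next lowest, and an interquartile range of 1.80 log2 against 3.03 to 3.66. It is called the failed array. It stayed in as planned, so means, SDs and donor counts of CIS at year 1 include it unless stated. Gene counts without it are given as well. The other settings were other filters on dim probe sets, other scalings, all probe sets, first arrays only, array weights, robust moderation, the 3' minus 5' signal of the ACTB and GAPDH control probe sets as covariates, fits with and without the donor block, and year-1 arrays with the same time code (T2) as the controls. Leaving out the failed array or each donor in turn, the 2 leading components of the hybridisation spike-in probe sets, and scores of other-cell markers with HBB as covariates were chosen after the data were seen.

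The fits were tested on simulated data built on the donors of each comparison and 12638 genes. Of 100 genes shifted by 1 log2, 94 were recovered for CIS against controls at baseline, 92 at year 1, 100 for CIS donors over time, 90 for control donors over time and 93 for the difference of changes. Of 100 genes shifted by 0.5 log2, 70, 41, 90, 38 and 32 were recovered in the same order. Unchanged genes made up 5.41%, 5.63%, 6.39%, 2.99% and 5.97% of the calls in that order. The simulated noise was independent between genes, so these shares need not hold for the real arrays. There, other splits of the donors gave up to 2900 calls at baseline.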

Results

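Expression was measured in CD4+ T cells, the helper and regulatory lymphocytes, of 37 CIS donors and 28 healthy control donors at baseline. At the follow-up about a year later, 33 CIS donors and 10 control donors were measured. The design gave a case-control comparison at each time point, a comparison of the time points within each group, and a comparison of the changes between the groups. The median correlation of an array with the other arrays was 0.932 for CIS at baseline, 0.936 for controls at baseline, 0.931 for CIS at year 1 and 0.929 for controls at year 1. The failed array, from 1 CIS donor at year 1, had a median correlation of 0.0535. The time to conversion to multiple sclerosis was not analysed here.

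The baseline comparison asked how CD4+ T cells of patients after a first attack differ from those of healthy people. CDK6, a kinase that drives cells through G1, had the largest increase, at 8.55 ± 0.94 log2 (SD, n = 37) in CIS and 6.66 ± 1.04 (n = 28) in controls. The difference was 1.89 (SE 0.24, adjusted p = 1.7e-09), and 35 of 37 CIS donors lay above the control mean. NABP1, a single-stranded DNA binding protein, was higher by 1.61 (SE 0.16, adjusted p = 2.5e-12, 36 of 37 donors), and RNF149, a ubiquitin ligase, by 1.44 (SE 0.14, adjusted p = 4.3e-13, 36 of 37 donors). The nuclear factor C1D was higher by 1.52 and the androgen-dependent hydrolase ADTRP by 1.48. The centrosomal proteins CETN3 and CEP350 were higher by 1.65 and 1.43, although 1 of 3 other probe sets of CEP350 had the opposite sign. The other leading genes were TMEM45B at 1.53, POLR1HASP at 1.52 and TRAPPC6B at 1.47. HBB, the beta chain of haemoglobin, had the largest decrease, from 10.20 ± 1.55 in controls to 6.61 ± 1.10 in CIS, a difference of -3.59 (SE 0.32, adjusted p = 8.6e-14, 37 of 37 donors). The class II antigen presentation gene HLA-DRA differed by -2.43 (SE 0.32, adjusted p = 3.7e-09, 36 of 37 donors) and HLA-DRB4, which not everyone carries, by -2.25 (SE 0.58, adjusted p = 0.00092, 29 of 37 donors). Genes of myeloid cells followed, with the lectin FCN1 at -2.38, the protease inhibitor CST3 at -2.23, the signalling adaptor TYROBP at -2.11 and the neutrophil-attracting chemokine CXCL8 at -2.11. The lipolysis inhibitor G0S2 differed by -2.27, and the cytotoxic cell genes CCL5 and NKG7 by -2.19 and -2.05.

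Of the 12638 genes tested, 2810 were higher and 3763 lower in CIS, 854 and 1255 of them by at least 1.5-fold. With scores of other-cell markers and HBB as covariates, 4287 genes were called, 3687 of them among the original calls. Under those covariates HLA-DRA (-1.15, adjusted p = 0.0869), HLA-DRB4 (-1.98, adjusted p = 0.144), CCL5 (-0.60, adjusted p = 0.469), CXCL8 (-1.10, adjusted p = 0.0760) and ATF3 (-0.83, adjusted p = 0.130) missed the threshold.

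Markers of other blood cells were lower in CIS at baseline. Of 19 measured monocyte markers, 17 were lower and 0 higher (17 lower when adjusted over the list alone), with a median of -1.19 (camera adjusted p = 3.9e-06). The inhibitory receptor LILRB2 differed by -1.19. Of 17 platelet markers, 16 were lower and 0 higher (16 when adjusted over the list alone; median -1.27, adjusted p = 5.9e-05). Among them were the receptor TREML1 at -1.70, the matrix protein SPARC at -1.82, the clotting factor subunit F13A1 at -1.74 and the platelet glycoprotein GP9 at -0.36. Of 17 cytotoxic lymphocyte markers, 13 were lower and 0 higher (15 lower when adjusted over the list alone; median -0.85, adjusted p = 5.9e-05). They included CTSW at -1.78, CST7 at -1.10 and the natural killer receptor NCR1 at -0.60. For these 3 lists the call was lost, with an adjusted p of 0.450 with an estimated correlation. Of 16 B cell markers, 7 were lower and 0 higher (median -0.34, adjusted p = 0.12), and of 8 dendritic cell markers, 7 were lower and 0 higher (median -0.49, adjusted p = 0.056), so neither list passed. Of 7 neutrophil markers 3 were lower (median -0.18, adjusted p = 0.24), and of the 3 measured erythroid markers 1, HBB, was lower (median -0.35, adjusted p = 0.11).

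**Figure D1:**
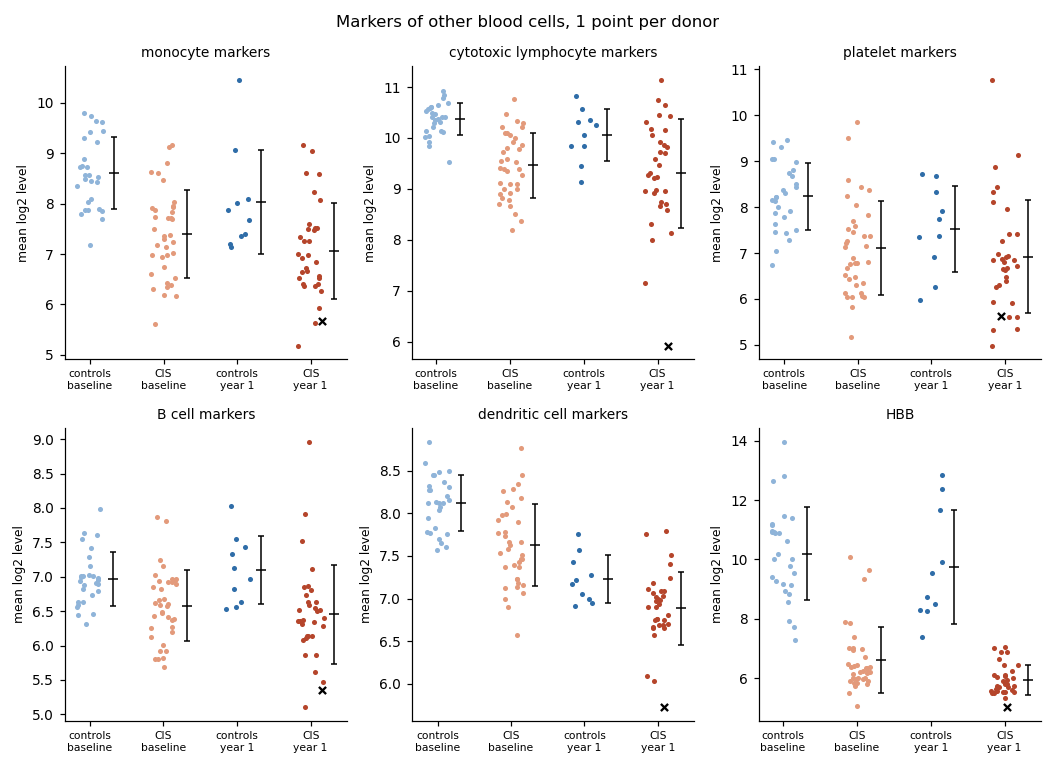
Mean log2 level of 5 marker lists of other blood cells, and the log2 level of HBB, with 1 point per donor in each group, bars at the mean ± SD, and a cross for the failed array. In CIS donors the monocyte, cytotoxic and platelet markers and HBB lay below those of controls at baseline, with HBB at 6.61 ± 1.10 against 10.20 ± 1.55.

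Genes induced by NF-kB, the transcription factor of inflammatory and antigen receptor signals, were lower in CIS at baseline beside those cell markers. Of 22 measured targets, 15 were lower and 2 higher (15 and 3 when adjusted over the list alone), with a median of -0.62 (adjusted p = 0.0011). The inhibitor NFKBIE differed by -1.05 in 37 of 37 donors, the inhibitor NFKBIA by -1.05, the adhesion molecule ICAM1 by -0.96 and the cytokine IL1B by -1.02. The higher members were BIRC2 at 0.43 and TNFAIP8 at 0.48, named after their values were seen, both of which restrain cell death. Of 33 immediate early genes, the fast responders to stimulation, 18 were lower and 4 higher (18 and 4 when adjusted over the list alone; median -0.36, adjusted p = 0.0385). The stress factor ATF3 differed by -1.86, the phosphatase DUSP2 by -0.96 and CSRNP1 by -0.73, while CD69 and MYC, singled out after their values were seen, were higher by 0.81 and 0.91. The adjusted p was 0.450 with an estimated correlation for the NF-kB targets and 0.588 for the immediate early genes. The immediate early list also missed the threshold with ACTB and GAPDH covariates (adjusted p = 0.107) or spike-in covariates (adjusted p = 0.0581). Of 43 cytosolic ribosomal proteins, 16 were higher and 7 lower (16 and 7 when adjusted over the list alone; median 0.05, adjusted p = 0.0058). Among the higher ones were RPL30 at 0.51, RPS23 at 0.86, RPS7 at 0.61 and RPS12 at 0.43, the last with an opposite sign in its other probe set. That list lost its call after quantile normalisation, where its median was -0.02 (adjusted p = 0.289), and its adjusted p was 0.450 with an estimated correlation. With no filter on dim probe sets, 16 lists passed in place of 6.

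**Figure D2:**
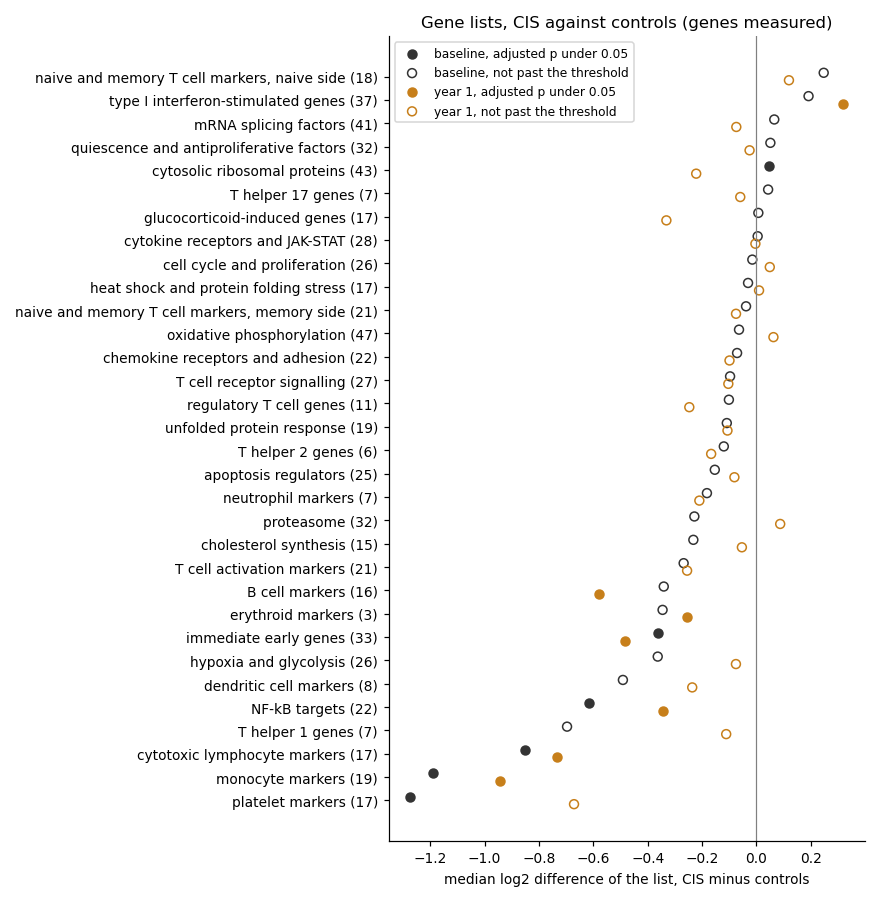
Median log2 difference of each gene list, CIS minus controls, at baseline (dark) and year 1 (orange), with the number of measured genes in brackets and filled points where camera gave an adjusted p under 0.05. Monocyte, cytotoxic, NF-kB and immediate early lists were filled on the negative side at both time points, with the monocyte markers at -1.19 and -0.94. With an estimated correlation these lists passed at neither time point.

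Factors that hold T cells in quiescence did not move as a group at baseline. Of 32 measured members, 11 were higher and 8 lower (12 and 9 when adjusted over the list alone; median 0.05, adjusted p = 0.125). TOB1, an antiproliferative protein of resting T cells, was at 10.58 ± 0.50 in CIS and 9.98 ± 0.70 in controls, higher by 0.61 (SE 0.15, adjusted p = 0.00037, 31 of 37 donors), and its other probe set had the opposite sign. On the donors with both time points the TOB1 difference was 0.34 (adjusted p = 0.113). CDKN1B, the cell cycle inhibitor p27, was higher by 0.46 (SE 0.07, adjusted p = 1.1e-07, 35 of 37 donors). The related BTG1 differed by 0.28 (adjusted p = 0.0584, 26 of 37 donors) and the quiescence factor KLF2 by 0.18 (adjusted p = 0.28, 19 of 37 donors). BTG1 passed with ACTB and GAPDH covariates (0.51, adjusted p = 0.000444), and KLF2 passed with array weights (0.54, adjusted p = 0.000127).

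**Figure D3:**
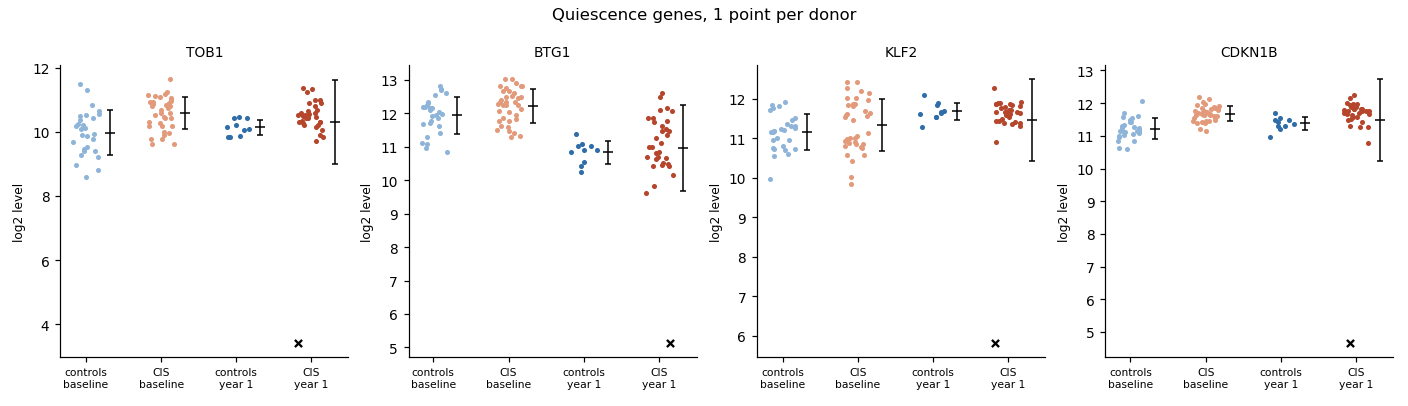
Log2 level of TOB1, BTG1, KLF2 and CDKN1B with 1 point per donor in each group, bars at the mean ± SD, and a cross for the failed array, which lies far below the other CIS donors at year 1. TOB1 was at 10.58 ± 0.50 in CIS and 9.98 ± 0.70 in controls at baseline, and BTG1 was lower at year 1 than at baseline in both groups.

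The year-1 comparison put the same question to the follow-up arrays. IFI44L, an interferon-stimulated gene, had the largest increase, at 7.79 ± 1.61 (n = 33) in CIS and 6.01 ± 0.96 (n = 10) in controls, a difference of 1.78 (SE 0.51, adjusted p = 0.035, 30 of 33 donors). TAFA1, a secreted chemokine-like protein, was higher by 1.62 (SE 0.27, adjusted p = 0.0011, 31 of 33 donors), TCEAL8 by 1.39 (adjusted p = 0.002, 33 of 33 donors) and CCR2, a receptor for monocyte-attracting chemokines, by 1.35 (adjusted p = 0.04, 29 of 33 donors). C1D and TMEM45B, which also led at baseline, were higher by 1.37 and 1.32. They were followed by MCOLN3, LOXL1-AS1, TCEAL2 and MIS18A at 1.36, 1.32, 1.24 and 1.21. HBB again had the largest decrease, at 5.95 ± 0.51 in CIS and 9.75 ± 1.91 in controls, a difference of -3.79 (SE 0.34, adjusted p = 1.8e-10, 33 of 33 donors). CXCL8 differed by -2.01 (SE 0.45, adjusted p = 0.011, 31 of 33 donors) and KLF4, a zinc finger factor that restrains proliferation, by -1.93 (SE 0.41, adjusted p = 0.0077, 32 of 33 donors). The myeloid genes FCN1, S100A12, S100A9 and TYROBP differed by -1.70, -1.58, -1.50 and -1.48, the immunoglobulin gene IGLC1 by -1.67, and CLIC3 and G0S2 by -1.54 and -1.40.

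At year 1, 384 genes were higher and 308 lower in CIS, 265 and 96 of them by at least 1.5-fold. Centring each array on its median gave 352 higher and 141 lower, which moved the share of higher calls from 55.5% to 71.4%. Without the failed array, 2345 genes were higher and 1537 lower. Leaving out donors in turn moved the count over 1.5-fold for 7 control donors, to 120 to 458 calls. It did so for 5 further CIS donors, to counts down to 437. Array weights gave 5799 calls, ACTB and GAPDH covariates 2853, spike-in covariates 1462, and the 75th percentile as the filter 152. On the 9 CIS donors whose year-1 arrays carried the same time code as the controls, 59 genes were called, 19 of them among the original calls. In that fit 26 of the 44 genes named for year 1 fell short, among them IFI44L, KLF4, CXCL8 and the others named above apart from HBB. After centring on the median 6 fell short, IGLC1, S100A12, TYROBP, PPP1R15A, NFKBIA and LILRB2. With other-cell marker scores as covariates limma called 0 genes, with 158 at an unadjusted p under 0.05, fewer than chance alone would give. The median SE rose from 0.191 to 0.366. CCR2, IGLC1, TYROBP, PPP1R15A, NFKBIA and HERC5 missed the threshold under each of the other filters on dim probe sets (with no filter at all, adjusted p from 0.0502 for CCR2 to 0.0615 for HERC5). S100A12 (adjusted p = 0.0593) and LILRB2 (adjusted p = 0.0558) missed it with no filter.

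Type I interferon-stimulated genes were higher in CIS at year 1 as a list. The list missed the threshold at baseline, with 15 higher and 7 lower (median 0.19, camera adjusted p = 0.0587). Its change over the year was not called different between CIS and control donors (median 0.03, camera adjusted p = 0.988). Of 37 measured, 3 were higher and 0 lower at year 1 (4 higher when adjusted over the list alone), with a median of 0.32 (adjusted p = 0.00022, and adjusted p = 0.995 with an estimated correlation). Besides IFI44L these were the RNA helicase DDX60 at 0.82 (adjusted p = 0.023) and the ISG15 ligase HERC5 at 0.67 (adjusted p = 0.049), while the RNA sensor IFIH1 differed by 0.49 (adjusted p = 0.067, and 0.0102 without the failed array). Without the failed array 14 were higher and 0 lower (17 when adjusted over the list alone; median 0.41, adjusted p = 0.00051), among them the kinase EIF2AK2 at 0.89 and RSAD2 at 1.19. Of 33 immediate early genes, 2 were lower, PPP1R15A by -0.82 and NFKBIA by -0.91 (5 when adjusted over the list alone; median -0.48, adjusted p = 0.00034). EGR1 at -1.25 (adjusted p = 0.063) and IER5 at -0.77 (adjusted p = 0.07) did not pass. With the failed array left out 12 were lower and 0 higher (median -0.39), EGR1 (adjusted p = 0.0279) and IER5 (adjusted p = 0.0206) among them. Of 22 NF-kB targets, 4 were lower and 0 higher (5 when adjusted over the list alone; median -0.34, adjusted p = 0.0068), with NFKBIE at -0.80 and the activation marker CD83 at -1.03. Leaving out the failed array gave 6 lower and 1 higher. For these lists the adjusted p was 0.995 with an estimated correlation. Among the 10 controls at year 1 a donor stood apart from the others for the interferon list, IFI44L, the NF-kB targets and NFKBIA. Leaving out each control donor in turn, a test added after the data were seen, gave interferon medians of 0.29 to 0.34 and NF-kB medians of -0.37 to -0.26, and both lists passed in 10 of 10 fits, but IFI44L (1.51 to 1.91) was called in 5 of 10.

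Markers of 4 other cell types were lower in CIS at year 1 as lists. Of 19 monocyte markers, 6 were lower and 0 higher (15 lower when adjusted over the list alone; median -0.94, adjusted p = 1.2e-06), with LILRB2 at -0.94, and without the failed array 13 were lower. Of 16 B cell markers, 2 were lower, IGKC by -1.21 and the B cell factor PAX5 by -1.38 (7 when adjusted over the list alone; median -0.58, adjusted p = 0.00025). CD79A at -0.57 and VPREB3 at -0.59 had adjusted p of 0.058 and 0.06. There were 7 lower without the failed array, with CD79A (adjusted p = 0.0246) and VPREB3 (adjusted p = 0.0265) among them. Of 17 cytotoxic lymphocyte markers limma called 0 (0 when adjusted over the list alone, 7 lower at an unadjusted p under 0.05), with a list median of -0.73 (adjusted p = 0.00058) and CTSW at -0.86, GZMH at -1.29 and CST7 at -1.14. CTSW at -0.75 (adjusted p = 0.0342) and CST7 at -0.97 (adjusted p = 0.0294) were called without the failed array. For these 3 lists the adjusted p was 0.995 with an estimated correlation. The 3 measured erythroid markers, HBB with SLC4A1 at -0.26 and ALAS2 at -0.23, had a median of -0.26 (adjusted p = 0.00022), with 1 called lower (3 when adjusted over the list alone), and this list kept its call (adjusted p = 0.0384 with an estimated correlation). All 3 were called lower without the failed array, but the list missed the threshold (adjusted p = 0.1795 with an estimated correlation). Platelet markers (17 measured, median -0.67, adjusted p = 0.0578), dendritic cell markers (8, median -0.24, adjusted p = 0.227) and neutrophil markers (7, median -0.21, adjusted p = 0.439) did not pass at year 1.

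Of 32 measured quiescence factors, 0 were higher and 1 lower at year 1 with all arrays (2 and 3 when adjusted over the list alone). The list median was -0.03 (camera adjusted p = 0.98). The member called was KLF4, and none of TOB1, BTG1, KLF2 and CDKN1B passed. TOB1 differed by 0.16 (SE 0.40, adjusted p = 0.83), BTG1 by 0.13, KLF2 by -0.21 and CDKN1B by 0.11, and the failed array widened the spread of each. Without it TOB1 was higher by 0.38 (adjusted p = 0.0307) and CDKN1B by 0.32 (adjusted p = 0.0141), while BTG1 differed by 0.32 (adjusted p = 0.296) and KLF2 by -0.04 (adjusted p = 0.766).

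The differences between CIS and controls at the 2 time points were compared on the 32 CIS and 10 control donors measured at both. Across the 12638 genes, which are not independent replicates, they correlated at 0.649 (Spearman rho 0.633), and 76.0% of genes had the same sign. In 100 permutations of the group over donors the highest correlation was 0.608, so p was 0.0099, the smallest that 100 draws can give. The correlation was 0.644 without the failed array, 1 draw was larger (0.672) and p was 0.0198. Of the calls on all donors, 241 genes were higher at both time points, C1D and TMEM45B among them, and 157 were lower, HBB among them, where independent lists would share 85.4 and 91.7. In opposite directions 13 genes were called. At both, 1397 genes were higher and 743 lower without the failed array, where independent lists would share 521 and 458, and 147 were called in opposite directions. The comparisons share donors, so independent lists do not give the overlap expected by chance, and the overlap in permuted donors was not counted.

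Within CIS donors, year 1 was compared with baseline in the 32 donors with both time points. THRAP3, a component of splicing and transcription complexes, rose from 9.15 ± 0.92 to 11.07 ± 0.81, a change of 1.92 (SE 0.22, adjusted p = 1e-08, 31 of 32 donors). LTBP3, which binds latent TGF-beta, rose from 7.65 ± 1.48 to 9.66 ± 0.90 (adjusted p = 1.8e-06, 28 of 32 donors). The synaptic adhesion protein LRFN3 rose by 1.74 (SE 0.17, adjusted p = 8.5e-10, 31 of 32 donors) and the actin regulator CORO1A by 1.98 (SE 0.39, adjusted p = 8.5e-05, 28 of 32 donors). EHBP1L1 rose from 6.33 ± 1.28 to 8.33 ± 1.28 (27 of 32 donors). The other leading increases were PHB1 at 1.98, CCDC85B at 1.90, GNB2 at 1.79, the oxidase subunit CYBA at 1.77 and TMEM160 at 1.74. FOSB, a component of the AP-1 transcription factor, fell from 11.75 ± 1.13 to 8.53 ± 1.99, a change of -3.22 (SE 0.39, adjusted p = 3.6e-08, 28 of 32 donors). SKIL, a repressor of TGF-beta signalling, changed by -2.22 (SE 0.17, adjusted p = 1.2e-11, 32 of 32 donors), KLF4 by -2.64 (SE 0.28, adjusted p = 2.7e-09, 29 of 32 donors) and EGR1 by -2.01 (SE 0.30, adjusted p = 1.4e-06, 28 of 32 donors). ADAM28 changed by -2.10, TSPAN13 by -2.02, RUBCNL by -1.97, the monocyte gene MS4A7 by -1.91, the translation release factor GSPT1 by -1.90 and the lymphocyte adaptor SH2D1B by -1.89.

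In CIS donors 3463 genes rose and 3116 fell, 1282 and 1524 of them by at least 1.5-fold. Without the failed array 4465 rose and 3265 fell, and the 75th percentile as the filter gave 4137 calls. With other-cell marker scores as covariates 273 genes were called, 265 of them among the original calls, and the median of all genes moved to 0.26. Under those covariates most named genes of this comparison missed the threshold, FOSB for example at -0.94 (adjusted p = 0.577), and the phosphatase DUSP1 changed sign, from -0.82 to 0.20.

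Immediate early genes fell in CIS donors. Of 33 measured, 19 fell and 0 rose (21 when adjusted over the list alone), with a median of -0.45 (adjusted p = 0.00013, and adjusted p = 1 with an estimated correlation). FOS changed by -1.70 in 27 of 32 donors and the kinase SIK1 by -1.21, with an opposite sign in its other probe set. Of 17 glucocorticoid-induced genes, 10 fell and 0 rose (10 when adjusted over the list alone; median -0.44, adjusted p = 0.023). Among them were the kinase SGK1 at -1.83 in 32 of 32 donors, the insulin receptor substrate IRS2 at -1.20, the mRNA decay factor ZFP36 at -0.67 and DUSP1 at -0.82, the last with an opposite sign in 1 of 2 other probe sets. Of 41 mRNA splicing factors, 17 fell and 3 rose (16 and 3 when adjusted over the list alone; median -0.38, adjusted p = 0.032). Among those that fell were SNRPE at -1.25, SRSF10 at -1.13, SRSF4 at -0.77 and RBM25 at -0.95 in 32 of 32 donors, although 1 of 6 other probe sets of RBM25 had the opposite sign. When the failed array was left out 22 fell and 9 rose, and the median was -0.16 (adjusted p = 0.0177). For both of these lists the adjusted p was 1 with an estimated correlation. The splicing list missed the threshold after quantile normalisation (adjusted p = 0.121) or with spike-in covariates (adjusted p = 0.0733). Of 8 dendritic cell markers, 6 fell and 0 rose (6 when adjusted over the list alone; median -0.76, adjusted p = 0.014, and adjusted p = 0.381 with an estimated correlation). They included the transcription factor TCF4 at -1.79, the IgE receptor chain FCER1A at -1.19, LILRA4 at -0.80 and CD1C at -0.67. BTG1 fell from 12.31 ± 0.45 to 10.93 ± 1.29, a change of -1.38 (SE 0.22, adjusted p = 3.2e-06, 27 of 32 donors). TOB1 at -0.26 (adjusted p = 0.378), CDKN1B at -0.18 and KLF2 at 0.11 did not pass, and without the failed array TOB1 was at -0.02, CDKN1B at 0.04 and KLF2 at 0.33 (adjusted p = 0.0125).

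Within control donors, the same comparison was made in 10 donors. SKIL fell from 10.49 ± 0.48 to 7.44 ± 0.37, a change of -3.05 (SE 0.16, adjusted p = 2.3e-08) in 10 of 10 donors. The elongation factor ELL2 changed by -2.59 (SE 0.13), the chromatin protein ATAD2 by -2.46 (SE 0.10, adjusted p = 2e-09), FOSB by -2.14 (SE 0.25, adjusted p = 9.5e-06) and CREM, a cyclic AMP responsive factor, by -2.11 (SE 0.14), each in 10 of 10 donors. FBXO8, TXNDC16, NAMPT, CNOT6L and TNFRSF21 changed by -2.12, -2.06, -2.05, -2.03 and -2.00. The increases were led by SLC60A2, a glucose transporter, at 1.75 (SE 0.12, adjusted p = 2.4e-07, 10 of 10 donors), with an opposite sign in its other probe set. The zinc finger genes ZNF573 and ZNF248 followed at 1.71 and 1.64, the ephrin receptor EPHA1 at 1.69 and the signalling regulator RGS14 at 1.63. SIMC1P1, with 1 of 2 other probe sets opposite, LRFN3, LEF1-AS1, PHLDB3 and the splicing factor PRPF31 rose by 1.65, 1.58, 1.57, 1.56 and 1.56.

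In control donors 3372 genes rose and 3243 fell, 1192 and 1700 of them by at least 1.5-fold. With ACTB and GAPDH covariates 3731 genes were called and with spike-in covariates 1361, and under the latter ZNF573, SIMC1P1, RGS14, LRFN3, PHLDB3, PRPF31, FOSB and TNFRSF21 missed the threshold. With other-cell marker scores as covariates, which left 3 residual degrees of freedom, limma called 0 genes. At an unadjusted p under 0.05 there were 183, fewer than chance alone would give, and TNFRSF21 and BNIP3L changed sign to 0.18 and 0.26.

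Of 33 immediate early genes, 19 fell and 4 rose in control donors (21 and 4 when adjusted over the list alone; median -0.52, adjusted p = 0.00043). They included IER5 at -1.15, the nuclear receptor NR4A3 at -1.90, ATF3 at -1.93 and SIK1 at -1.16, the last with an opposite sign in its other probe set. Of 22 NF-kB targets, 12 fell and 1 rose (13 and 1 when adjusted over the list alone; median -0.41, adjusted p = 0.008). Among those that fell were CD83 at -1.38, REL at -0.96, BIRC2 at -0.49 and NFKB2 at -1.80, whose other probe set had the opposite sign. Of 26 hypoxia and glycolysis genes, 11 fell and 1 rose (11 and 1 when adjusted over the list alone; median -0.21, adjusted p = 0.03). They included the glycolysis activator PFKFB3 at -1.56, LDHA at -0.60, ANKRD37 at -0.75 and BNIP3L at -0.58. Of 8 dendritic cell markers, 6 fell and 0 rose (6 when adjusted over the list alone; median -0.75, adjusted p = 0.031). Among them were TCF4 at -1.68, FCER1A at -1.52, LILRA4 at -0.84 and CD1C at -0.77. For these 4 lists the adjusted p was 0.506 with an estimated correlation. Of 43 ribosomal proteins, 28 rose and 1 fell (29 and 1 when adjusted over the list alone; median 0.21, adjusted p = 0.0023, and adjusted p = 0.626 with an estimated correlation). Among them were RPS15 at 0.62, RPL24 at 0.53, RPS14 at 0.33 and RPL32 at 0.33. The ribosomal list missed the threshold after quantile normalisation (adjusted p = 0.0516), and of the 5 lists 2 passed with quantile normalisation and 2 with ACTB and GAPDH covariates. BTG1 fell from 11.74 ± 0.64 to 10.83 ± 0.34, a change of -0.91 (SE 0.17, adjusted p = 0.00052, 9 of 10 donors), and 1 of 2 other probe sets had the opposite sign. KLF2 rose by 0.46 (SE 0.12, adjusted p = 0.0055, 9 of 10 donors), but with spike-in covariates its change was -0.10 (adjusted p = 0.769). BTG1 missed the threshold with ACTB and GAPDH covariates (-0.60, adjusted p = 0.0764) or spike-in covariates (-1.13, adjusted p = 0.0580). TOB1 at -0.11 and CDKN1B at 0.23 did not pass.

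The year-1 changes of the groups, which share no donor, ran together. Across genes, which are not independent replicates, they correlated at 0.715 (Spearman rho 0.711), and the highest correlation in 100 draws that flipped the sign of whole donors was 0.596. In both groups 2208 genes rose, LRFN3 among them, and 1952 fell, SKIL, FOSB and BTG1 among them. Independent lists would share 924 and 800, and 151 genes were called in opposite directions. Leaving out the failed array gave 2613 that rose, 1991 that fell and 267 opposite, and the correlation was 0.7099.

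**Figure D4:**
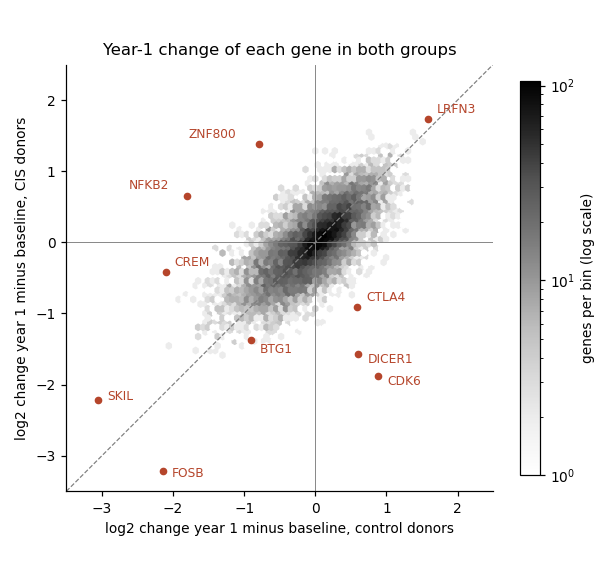
Log2 change from baseline to year 1 of each of 12638 genes in control donors (horizontal) and CIS donors (vertical), as hexagonal bins shaded by the number of genes on a log scale, with the line of equal change dashed. SKIL, FOSB, BTG1 and LRFN3 changed in the same direction in both groups, while CDK6, DICER1, CTLA4, NFKB2, CREM and ZNF800 lay away from the line, across genes that correlated at 0.715.

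The last comparison asked which genes changed differently in CIS and in control donors over the year. CDK6 changed by -1.87 ± 1.31 (SD, n = 32) in CIS and 0.88 ± 0.79 (n = 10) in controls, a difference of -2.75 (SE 0.42, adjusted p = 9.2e-05, 31 of 32 CIS donors below the control mean), although 1 of 3 other probe sets had the opposite sign. DICER1, the nuclease that makes microRNAs, changed by -1.57 ± 0.93 against 0.61 ± 0.56, a difference of -2.17 (SE 0.31, adjusted p = 4.2e-05, 32 of 32 donors). CTLA4, the inhibitory receptor of activated and regulatory T cells, changed by -0.91 ± 0.92 against 0.59 ± 0.43, a difference of -1.50 (SE 0.30, adjusted p = 0.0044, 32 of 32 donors). The failed array is among the 32, and without it CTLA4 changed by -0.78 ± 0.51 in CIS. The differences were then -2.66 for CDK6, -2.10 for DICER1 and -1.37 for CTLA4. CEP350 differed by -1.61, DPH6 by -1.55, ZNF573 and the kinase ITPKB by -1.48 each. IGIP differed by -1.44, NIBAN1 by -1.35 and BRD10 by -1.34, although 1 other probe set each of CEP350, ITPKB and BRD10 had the opposite sign. In the other direction ZNF800 changed by 1.38 ± 0.88 against -0.79 ± 0.82, a difference of 2.17 (SE 0.30, adjusted p = 3.3e-05, 31 of 32 donors). NFKB2, the precursor of an NF-kB subunit, changed by 0.66 ± 1.84 against -1.80 ± 1.03, a difference of 2.46 (SE 0.57, adjusted p = 0.014, 29 of 32 donors). ANKRD36 differed by 2.44, the cell death effector BAX by 2.09, the chaperone partner CDC37 by 1.87, THRAP3 and DLST by 1.83 each, the kinase PRKCD by 1.78, the proteasome ATPase PSMC3 by 1.73 and CREM by 1.69 (adjusted p = 0.009).

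**Figure D5:**
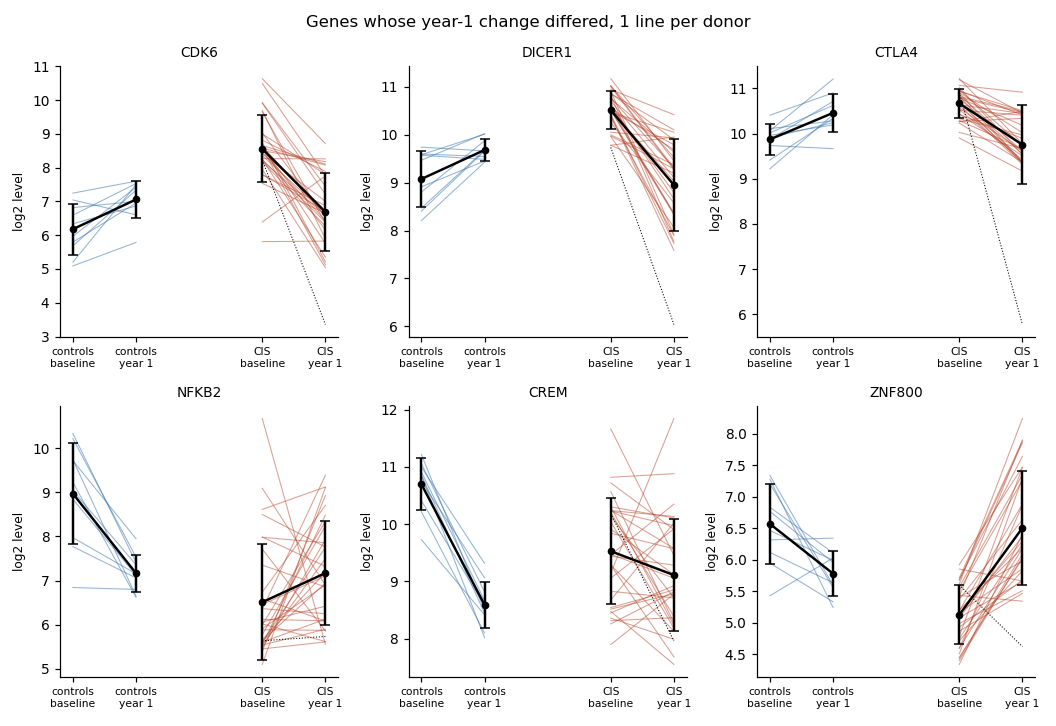
Log2 level of 6 genes at baseline and year 1, with 1 thin line per donor, black points and bars at the mean ± SD of each group, and a dotted line for the CIS donor with the failed array. CDK6, DICER1 and CTLA4 fell in CIS donors by mean changes of -1.87, -1.57 and -0.91, while in control donors they changed by 0.88, 0.61 and 0.59.

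For 162 genes the change was higher in CIS and for 80 it was lower. Without the failed array these counts were 838 and 324. Leaving out donors in turn moved the total over 1.5-fold for 7 control donors (127 to 158 calls) and 1 further CIS donor (372 calls). Array weights gave 3562 calls, spike-in covariates 1170 and the 75th percentile as the filter 121. With ACTB and GAPDH covariates NFKB2 (1.33, adjusted p = 0.0818), BAX, CDC37, PRKCD, PSMC3 and IGIP missed the threshold, and in a model of all arrays with the donor as a random block, which called 667 genes, CREM did (1.06, adjusted p = 0.0663). With other-cell marker scores as covariates ZNF573 (-1.35, adjusted p = 0.0784) and IGIP (-1.40, adjusted p = 0.101) missed it.

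Of 22 NF-kB targets, the change of 1, NFKB2, was higher in CIS (4 when adjusted over the list alone; median 0.40), while ICAM1 at 0.75, REL at 0.82 and IL1B at 0.59 did not pass over all genes. With the failed array left out 3 were higher, with ICAM1 (0.78, adjusted p = 0.0153) and IL1B (0.56, adjusted p = 0.0272) among them. Of 11 regulatory T cell genes, the change of 1, CTLA4, was lower in CIS (1 when adjusted over the list alone; median -0.39), while IKZF2 at -0.85, IKZF4 at -0.62 and IL2RA, the high-affinity interleukin-2 receptor chain, at -0.39 did not pass. Of 43 ribosomal proteins limma called 0 (0 when adjusted over the list alone, 3 lower at an unadjusted p under 0.05; median -0.26), with RPS24 at -1.14, RPL9 at -1.01, RPS25 at -0.59 and RPS23 at -1.06, the last with an opposite sign in its other probe set. When the failed array was left out 9 were lower and 1 higher, with a median of -0.05, and RPS24 (-0.91), RPL9 (-0.77) and RPS23 (-0.81) were called. Each list had an adjusted p of 0.0199 and an adjusted p of 0.997 with an estimated correlation. After quantile normalisation camera passed 0 lists, with 6 at an unadjusted p under 0.05, and with spike-in covariates 0, with 5 at an unadjusted p under 0.05. The NF-kB list also missed the threshold without the failed array (median 0.44, adjusted p = 0.0627) and with ACTB and GAPDH covariates (adjusted p = 0.171). TOB1, BTG1, KLF2 and CDKN1B did not pass, at -0.16, -0.47, -0.35 and -0.42, nor without the failed array, at 0.08, -0.30, -0.14 and -0.19.

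Array quality followed the groups or times in 3 of 20 tests, and in 6 without the failed array. At baseline the 3' minus 5' log2 signal of ACTB was 7.44 ± 1.30 in CIS and 6.51 ± 0.99 in controls (permutation test, adjusted p = 0.0237), and that of GAPDH was 4.84 ± 2.12 and 3.26 ± 1.01 (adjusted p = 0.0128), where a larger value marks RNA with shorter copies. In control donors the array median rose from 4.97 to 5.01 at year 1 (adjusted p = 0.0267, 9 of 10 donors). Without the failed array the year-1 array median was also lower in CIS than in controls, by 0.0495 (permutation test, adjusted p = 0.0118). The interquartile range then rose over time in CIS donors by 0.115 (adjusted p = 0.0118). The GAPDH signal rose in control donors by 1.33 (adjusted p = 0.0456 in that set of tests). The mean log2 signal of the hybridisation spike-in probe sets, which carry no sample RNA, rose in control donors by 0.45 (permutation p = 0.00204, 10 of 10 donors) and in CIS donors differed by 0.03 (p = 0.825, higher in 16 of 32 donors). At baseline it was higher in CIS by 0.28 (p = 0.00318).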

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

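Of the tests in this part, those of monocyte against B cell markers, of the spike-in signal, of cell marker covariates, of the make-up of the highest other split, and of the failed array left out were chosen only after the results they measure had been seen.

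CDK6 (-2.75), DICER1 (-2.17), CEP350 (-1.61), DPH6 (-1.55), CTLA4 (-1.50), ZNF573 (-1.48), ITPKB (-1.48), IGIP (-1.44), NIBAN1 (-1.35) and BRD10 (-1.34) changed differently over the year in CIS and control donors, as did NFKB2 (2.46), ANKRD36 (2.44), ZNF800 (2.17), BAX (2.09), CDC37 (1.87), THRAP3 (1.83), DLST (1.83), PRKCD (1.78), PSMC3 (1.73) and CREM (1.69). They belong to 242 genes past the test of the difference itself. The same test over lists gave medians of -0.39 for regulatory T cell genes, 0.40 for NF-kB targets and -0.26 for ribosomal proteins (adjusted p = 0.997 with an estimated correlation for each), and the ribosomal median was -0.05 without the failed array. CDK6, CEP350, DICER1 and CTLA4 were higher in CIS at baseline and NFKB2, ZNF800 and CREM lower, while at year 1 limma called no difference for these 7 genes with all arrays (CDK6 -0.35, adjusted p = 0.562, and NFKB2 0.03, adjusted p = 0.97). Without the failed array ZNF800 (0.76, adjusted p = 0.0302) and CTLA4 (-0.58, adjusted p = 0.0101) were called against their baseline direction, and CEP350 (0.34, adjusted p = 0.0200) along it. Of 100 splits of the donors, 2 gave as many genes, the real one included. Leaving out 1 of the 7 control donors that moved the count over 1.5-fold gave 127 to 158. The highest other split gave 2616, so the count of 242 does not exclude chance. That split placed 2 of the 10 controls as in the real groups (2.38 by chance) and gave 2680 calls with the real group as a covariate and 1773 without the failed array, so it points to a structure of the donors that runs across the groups.

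In 11 of the 96 values tested among the 10 control donors at year 1, a donor stood apart from the others, where chance marks about 1 in 20 groups. It was not asked whether this was the same donor each time. The gap to the nearest donor over the whole range was 0.529 for ELL2, 0.577 for G0S2, 0.542 for IFI44L, 0.525 for NAMPT, 0.531 for NFKBIA, 0.575 for RPS14 and 0.486 for SIMC1P1. It was 0.532 for the list of interferon-stimulated genes, 0.641 for the NF-kB targets, 0.508 for the 3' minus 5' signal of GAPDH and 0.635 for the array interquartile range.

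Of 3939 probe sets with no gene name, which the comparisons above did not use, limma called 1709 at baseline, 1079 higher and 630 lower in CIS. Called were 43.4% of them, against 52.0% of named genes, and 63.1% of their calls were higher in CIS, against 42.8% for named genes.

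Monocyte, platelet and cytotoxic markers and HBB were lower in CIS at baseline. Other blood cells carried over into the control samples could explain these markers. Of the 6513 calls outside the marker lists, 56.5% (3678) kept their sign and threshold with the marker scores as covariates. That argues against carry-over as the source of all other calls only as far as these scores measure it. A single difference in T cell purity would lower every other cell type in CIS. The median of monocyte minus B cell markers was -0.85, against -0.47 to 0.47 when markers were permuted (p = 2.7e-04). The lists thus moved by unequal log2 amounts. That does not exclude a single difference, since equal carry-over need not give equal log2 shifts. In controls at baseline the monocyte markers averaged 8.60 and the B cell markers 6.97. For the NF-kB targets carry-over stays open, since the list kept 96.2% of its median under the covariates (-0.59 against -0.62, 22 genes) but resampled members gave 28.9% to 131%, and 9 of the 15 lower calls were kept, with CCL4 moving from -1.29 to -0.18, PLEK from -0.69 to 0.28 and NFKB2 from -2.00 to -2.60. Also open is which cells differed, and CIS itself as the cause was not tested. In 1 of the 100 splits, the real one, as many genes were called at baseline (6573, highest other 2900). That argues against chance, at the smallest share that 100 splits can give.

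SKIL, FOSB and BTG1 fell in both groups over the year. A difference between the arrays or the handling of the time points that reached both groups remains a possible explanation, with a correlation across genes of 0.715 against at most 0.596 in 100 sign flips of whole donors. Array hybridisation could account for part of the change in controls, where the spike-in signal rose by 0.45 (p = 0.00204), but in CIS donors it moved by 0.0261 (p = 0.825). In the 16 CIS donors whose spike-in signal fell, 99.04% of the 4160 genes changed alike in both groups kept their direction. Resampled donors gave 89.5% to 99.3%. These genes were chosen by their change in all CIS donors, the 16 included, so that share could hardly be low. It does not exclude hybridisation as a source of the shared part. Controls kept 1277 of 6615 calls with spike-in covariates. For CIS donors 1 of the 100 splits, the real one, reached 6579 genes (highest other 0). For controls 1 of the 100 reached 6615 (highest other 4043, in a split that matched the real one in 9 of the 10 controls). Both argue against chance, at the smallest share that 100 splits can give. A change in other blood cells stays open, since with marker scores as covariates 4142 of these genes, marker lists left out, kept a median of 67.6% of their CIS change (quartiles 12.4% and 112%), and 219 stayed called as the median standard error rose from 0.138 to 0.303.

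HBB and C1D differed between CIS and controls at both time points, but more genes were called at baseline (6573) than at year 1 (692). Leaving out the failed array alone raised the year-1 count to 3882, the larger part of the gap. The lower number of donors could account for part of the rest, as the donors with both time points gave 4912 calls at baseline, a ratio of 1.27 to the count without the failed array. With the ACTB and GAPDH covariates 86.2% of the baseline calls (5663) kept sign and threshold. That argues against 3' bias, as far as these transcripts measure it, as the source of most baseline calls. The year-1 count rose with the same covariates, so the part of 3' bias in the gap stays open. The differences of the 2 time points correlated at 0.649, against at most 0.608 in 100 permutations (0.644 with 1 larger draw, 0.672, without the failed array). Differences that recur at year 1 cannot come from the baseline arrays alone, so the correlation does not test such an artefact. An artefact present at both time points stays open, as does one that added calls at baseline. At year 1, 1 of the 100 splits, the real one, reached 692 genes, with 674 in the highest other. Leaving out 1 of the 7 control donors that moved the count over 1.5-fold gave 120 to 458, below that other split. The count of 692 thus does not exclude chance. Without the failed array that split gave 779 calls, against 3882 for the real groups, but the remaining splits were not run without it. A change of CIS donors towards controls stays open as untested.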

How the results depend on the processing

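Leaving out the failed array or single donors, spike-in covariates and cell marker covariates were chosen after seeing the data. Over 203 results for named genes, 2488 of 2801 alternative values stayed on their side of the threshold. Those called in both fits also kept their direction, but values that missed the threshold in both were counted whatever their sign. TOB1 for the difference of changes, for example, went from -0.16 to 0.08 without the failed array. A further 228 values fell short of the threshold, 79 newly passed, and 6 reversed with a call in the main or the alternative fit. Over 25 results for lists 119 of 178 kept direction and call and 59 fell short. The reversed values were G0S2 at year 1 (0.0301 with cell marker covariates, and 0.0308 with the failed array left out as well), DUSP1 in CIS over time (0.20 with cell marker covariates), KLF2 in controls over time (-0.10 with spike-in covariates), and TNFRSF21 (0.18) and BNIP3L (0.26) in controls with cell marker covariates.

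Testing all probe sets separately gave 13739 calls at baseline, 1981 at year 1, 14269 in CIS over time, 13819 in controls and 1249 for the difference of changes. Requiring at least 1.5-fold left 2109, 361, 2806 and 2892 in the first 4 of these. With the 75th percentile as the filter, calls were 152 at year 1, 4137 in CIS over time and 121 for the difference. Cell marker covariates gave 4287 at baseline, 0 at year 1 (limma, 158 at an unadjusted p under 0.05), 273 in CIS over time and 0 in controls (183). With the failed array left out as well they gave 0 at year 1 (372 at an unadjusted p under 0.05), 291 in CIS over time and 849 for the difference. Each of these unadjusted counts was lower than chance alone would give. Leaving out the failed array alone gave 3882 at year 1, 1162 for the difference and 6 array quality measures in place of 3. Year-1 calls were 5799 with array weights, 2853 with ACTB and GAPDH covariates, 1462 with spike-in covariates and 59 with the CIS arrays of the T2 label. In controls over time ACTB and GAPDH covariates gave 3731 and spike-in covariates 1361, and for the difference array weights gave 3562, the donor as a random block over all arrays 667 and spike-in covariates 1170. Without the donor block or pairing, calls were 6583 in CIS over time, 6401 in controls and 257 for the difference, and of the named genes ICAM1 newly passed for the difference (adjusted p = 0.0481) while no call was lost. Leaving out each donor in turn gave 120 to 3882 calls at year 1 and 127 to 1162 for the difference, both highest values without the failed array.

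With an estimated correlation camera passed 0 lists at baseline, 1 at year 1, and 0 in CIS over time, in controls and for the difference, with 1 list at an unadjusted p under 0.05 in each comparison. With the failed array left out as well it passed 0 lists at year 1, in CIS over time and for the difference (1, 1 and 2 at an unadjusted p under 0.05). With no filter 16 lists passed at baseline, 9 in controls over time and 6 for the difference. In controls over time 2 lists passed with ACTB and GAPDH covariates, 2 with quantile normalization and 9 with spike-in covariates, and for the difference camera passed 0 with quantile normalization (6 at an unadjusted p under 0.05) and 0 with spike-in covariates (5). Apart from the limit of 1.5-fold, which removes calls by construction, the cause was not tested. The pseudocount on a log scale could not be varied in values given as log2 and was not run. Genes with signal near background, under the median of all probe sets, were not tested, which limits what dim genes can show.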

Other observations

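The test of the zinc finger family and the fits without the failed array were chosen only after the results they concern had been seen.

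The scores of 4 lists varied more between CIS donors than between control donors at baseline, as did whole arrays. The heat shock and protein folding genes, which help proteins fold under stress, had an SD of 0.472 in CIS and 0.184 in controls (17 genes, SD ratio 2.57, adjusted p = 0.00096). The proteasome genes, which build the particle that degrades proteins, had an SD ratio of 2.15 (32 genes, adjusted p = 0.00629), the cytotoxic lymphocyte markers 1.94 (adjusted p = 0.0024) and the memory side of the T cell markers 1.77 (adjusted p = 0.0076). Of 32 lists 4 were wider and 0 narrower in CIS, by permutation of donors, and 25 ratios were above 1. The interferon-stimulated genes had a ratio of 3.01 (p = 0.0362, adjusted p = 0.104). With the median in place of the mean of the standardised members, 6 lists were wider in CIS. The widening was not set apart from a wider spread of the arrays, since pairs of CIS donors differed by a median of 0.398 log2 over the tested genes against 0.280 for controls. The array interquartile range had an SD of 0.143 against 0.0714, and the 3' minus 5' signal of GAPDH 2.12 against 1.01.

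Genes of oxidative phosphorylation were higher in CIS at year 1 once the failed array was left out. Of 47 measured, 22 were higher and 1 lower (25 and 2 when adjusted over the list alone), with a median of 0.21 (adjusted p = 0.00011, and adjusted p = 0.770 with an estimated correlation). Of the regulatory T cell genes, CTLA4 at -0.58 (adjusted p = 0.0101), FOXP3 at -0.26 (adjusted p = 0.0201) and IKZF4 at -0.43 (adjusted p = 0.0411) were lower in CIS at year 1 in that fit. They were singled out after their values were seen, and of 11 measured the other 8 did not pass, IKZF2 at 0.03 and IL2RA at -0.11 among them, nor did the list (adjusted p = 0.0602). Proteasome genes joined the lists whose change differed between the groups in that fit, with 6 genes higher in CIS and 0 lower, a median of 0.34 and an adjusted p of 0.0127 (adjusted p = 0.998 with an estimated correlation). With other-cell marker scores as covariates and the failed array left out, limma called 0 genes at year 1, those of oxidative phosphorylation included. Of all genes 372 had an unadjusted p under 0.05, fewer than chance alone would give.

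The hypothesis was tested that zinc finger genes of the ZNF family were higher in CIS at baseline as a group. Of 345 measured, 124 were higher and 84 lower, with a median of 0.07, and camera gave p = 0.0106 with its preset correlation but 0.1795 with an estimated correlation. The members move with each other too closely to set the family apart from other genes. The further hypothesis that long genes were higher in CIS gave a Spearman rho of 0.194 between genomic length and the baseline difference across genes, of which 99.9% had a length. Genes are not independent replicates, and permutations of the donor labels gave -0.238 to 0.215 in their central 90% and up to 0.287, so a link with length was not shown.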
